A study of Homo sapiens with 32 samples.

How the data were processed

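The series holds 32 samples of MDA-MB-231, an established triple-negative breast cancer cell line. Cells were controls or were treated for 24 h with an EZH2 inhibitor, a p38 MAP kinase inhibitor (labelled P38i) or both (labelled combo). The group with the EZH2 inhibitor alone is EP7 in the sample titles and is called EPZ here. For each of the 4 groups there were 4 ChIPmentation libraries for H3K27me3, the repressive histone mark made by the methyltransferase EZH2, and 4 libraries made with IgG. The extract protocol names the IgG immunoprecipitation as the input; the 16 IgG libraries had no file used here. The labels do not say whether replicates of a group were separate cultures, so the spread between them may be technical.

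The deposited files are 1 list of islands (enriched regions) per H3K27me3 library, and per the labels they hold only the start and end of each island on build hg38, with no other unit, score, count or p-value. The authors named FastQC, Trim Galore, cutadapt, Bowtie2 2.3.4.1, Picard, SAMtools 1.2, bedtools 2.28.0 and the island caller SICER. The order of these steps, the SICER version and the caller settings are not given in the sources used here. In the files, island bounds fell on windows of 200 bp, the shortest island was 200 bp, and the smallest gap between islands was 800 bp. The 16 lists held 1069155 islands. Read depth is unknown, so no interval from counts can be given, and every value below describes what was called, not the amount of the mark.

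Islands on chromosomes 1 to 22 and X were used. Per library, the number of islands, the covered length and the median island width were computed. Groups of 4 libraries were compared with 2-sided exact permutation tests over 70 arrangements, whose smallest p is 0.0286, and 15 such tests were adjusted together by the Benjamini-Hochberg method. The 8 libraries with an inhibitor were compared with the 8 without it by an exact permutation test, called a main effect below. Similarity of libraries was the Jaccard index over base pairs, within groups minus between groups. The genome was divided into bins of 10 kb, and a bin was gained or lost when at least 50% of it was covered in all 4 libraries of 1 group and in none of the other. Similarity and bins were set against all 35 splits of the 8 libraries.

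For each of 19970 protein-coding genes of the RefSeq annotation of GRCh38, the percent of the gene covered by islands was computed over the gene and 2.5 kb on each side. The plan had been a window around each gene start, but the gene table has no strand, so the gene span took its place after the data were seen. Genes with a mean coverage from 5 to 95% over the 16 libraries were tested, which left 4104; of the others, 15515 lay below and 351 above. Coverage was fitted with limma 3.58.1 (R 4.3.3, trend and robust options) in 1 fit of 16 libraries, with Benjamini-Hochberg adjustment within each contrast and a threshold of 0.05. The contrasts were EPZ, P38i and combo against control, combo against EPZ, combo against P38i, the main effect of each inhibitor, and their interaction (combo minus EPZ minus P38i plus control). Differences are in percentage points of gene length. The fit shares 1 spread per gene over the groups. Where a group lies at 0 in all its libraries, that spread may be too small for the other groups and the p-value too low. Coverage was checked against bedtools 2.31.1 over 500 genes, with a largest difference of 0. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

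The tests, the threshold, the rule for named genes, the alternatives and 18 gene lists were chosen before the data were examined, except where a choice is said to have come later. The lists were HOX genes, developmental regulators, signalling ligands, the p38 MAP kinase pathway, Polycomb subunits, inflammatory NF-kB targets, epithelial-mesenchymal transition and invasion genes, luminal epithelial genes, genes reported as silenced by EZH2 in tumours, antigen presentation and interferon genes, cell cycle genes, housekeeping genes, and neuronal, haematopoietic, hepatocyte, keratinocyte, germline and imprinted genes. Of the listed names, PALI1, UTY, NOV, LOR, H19, KCNQ1OT1 and MEG3 matched no gene in the table, and a gene listed under an older synonym too was counted once. For each list, the percent of members at least 50% covered was compared between groups in 54 exact permutation tests. The 15 lists with at least 3 tested members entered limma's camera test, with a preset correlation of 0.01 and, as an alternative, an estimated one. Named genes were the 10 with the largest rise and the 10 with the largest fall in each comparison among those past the threshold whose groups did not overlap, only the first where windows overlapped. The rule was written for comparisons with control and main effects and was also applied to combo against EPZ and against P38i. Where none passed, the 5 with the largest moderated t were given. Up to 4 members of each list by the same ranking were added, with EZH2 and MAPK14, the targets of the inhibitors. This rule named 94 genes, and the report gives values for part of them, chosen to cover each list and each direction.

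The model was tested on simulated data with the means and residual SDs of the real genes, noise independent between genes, and 50 changed genes of middle coverage per size. For 8 libraries against 8, changes of 10, 20, 30 and 40 points were recovered in 8, 58, 74 and 84% of genes, with 6 false calls. For EPZ against control the shares were 0, 22, 40 and 74%, with 3 false calls, and P38i against control, with no change planted, gave 0 calls. The simulation planted no shift of a whole library and no group at 0. Its false calls therefore do not give the rate of false calls in the real data. The alternatives covered island width, bin size and rule, flank, filters, transformation, covered length as a covariate, a replicate block, each library left out in turn and a fit of 2 groups alone. Gene ends in place of gene spans, the flanks around the span, lists trimmed to equal covered length by island width, and leaving out the narrowest library of each group were added after the data were seen.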

Results

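H3K27me3 islands were compared in 16 libraries of MDA-MB-231 cells, 4 per treatment. Control libraries held 62845 ± 9899 islands (SD, n = 4) that covered 589 ± 78.0 Mb, with a median width of 5.95 ± 1.43 kb. EPZ libraries held 68884 ± 11730 islands over 527 ± 56.4 Mb, with a median width of 4.95 ± 1.23 kb (n = 4). P38i libraries held 67059 ± 12087 islands over 620 ± 61.4 Mb, 5.65 ± 1.34 kb wide (n = 4). Combo libraries held 68496 ± 2211 islands over 565 ± 43.2 Mb, 5.05 ± 0.443 kb wide (n = 4). Single libraries ranged from 53290 to 85194 islands and from 474 to 674 Mb, and read depth is unknown. None of the 15 exact permutation tests of these 3 measures passed (lowest adjusted p = 0.857), which the design fixes for a single test, since the smallest p of 0.0286 cannot pass adjustment over 15. Covered length differed from control by -62.3 Mb in EPZ (exact p = 0.229), 30.8 Mb in P38i (exact p = 0.514) and -24.3 Mb in combo (exact p = 0.571). It differed by 38 Mb between combo and EPZ (exact p = 0.343) and by -55.1 Mb between combo and P38i (exact p = 0.143). The 8 libraries with the EZH2 inhibitor covered 546 ± 50.7 Mb against 605 ± 67.1 Mb in the 8 without it, a difference of -58.7 Mb (exact permutation p = 0.0668). The 8 libraries with the p38 inhibitor covered 593 ± 57.3 Mb against 558 ± 71.3 Mb, a difference of 34.4 Mb (exact permutation p = 0.30). With replicate number as a block the exact sign-flip p was 0.0391. Correlations of same-numbered libraries ran from -0.151 to 0.178 and those of different numbers from -0.204 to 0.164. This neither shows nor excludes that a number marks related libraries, and the labels do not say. No difference is therefore drawn from that pairing.

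**Figure D1:**
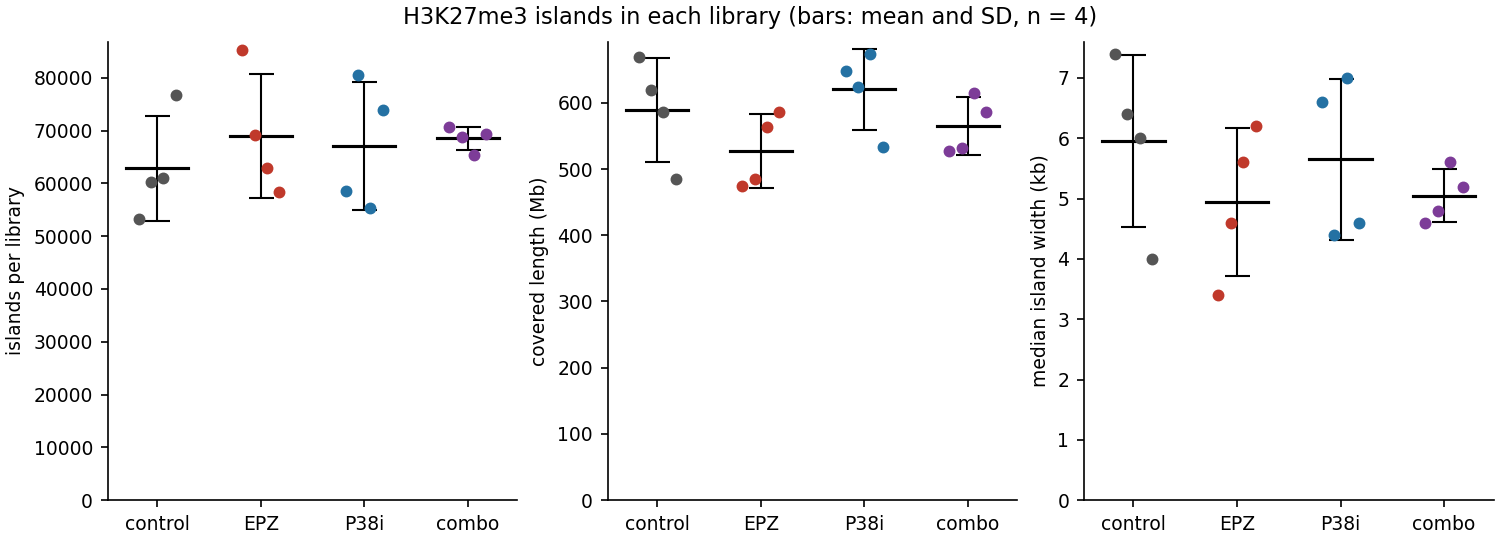
Covered length in Mb, number of islands and median island width in kb of each of the 16 libraries by treatment, with the mean and SD of each group of 4. The groups overlap in all 3 measures; single libraries cover from 474 to 674 Mb.

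The lists differed in how many members carried the mark. Over the 16 libraries, the mean percent of list members at least 50% covered was 37.8% for keratinocyte genes, 34.0% for neuronal genes, 25.0% for hepatocyte genes, 22.2% for signalling ligands and 19% for haematopoietic genes. It was 14.3% for developmental regulators, 14.1% for antigen presentation and interferon genes, 12.5% for luminal epithelial genes, 11.7% for genes reported as silenced by EZH2 and 11.6% for germline genes. It was 8.38% for inflammatory NF-kB targets, 3.39% for imprinted genes, 2.22% for the p38 pathway, 1.56% for Polycomb subunits and 1.32% for cell cycle genes. Housekeeping genes stood at 2.5% in every library and invasion genes at 0. HOX genes, classic Polycomb targets in other cells, stood at 2.24%, with 27 of 39 uncovered in all 16 libraries. EZH2 and MAPK14, the targets of the inhibitors, had no island in any library. None of the 54 exact permutation tests of these shares against control passed, which the design fixes for a single list: the smallest p of 0.0286 cannot pass adjustment over 54 tests. Luminal genes reached that smallest p in EPZ, at 8.75% against 15.6% in control (exact p = 0.0286, adjusted p = 1).

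EPZ against control asked what 24 h of the EZH2 inhibitor did to the islands. Coverage fell over 125 genes and rose over 5. CGA, the shared alpha subunit of the glycoprotein hormones (chromosome 6, 87085498 to 87095106), went from 81.2% ± 11.2 covered in control to 26.4% ± 18.0 in EPZ (SD, n = 4; adjusted p = 0.0105). GPR65, a proton-sensing receptor of immune cells, went from 82.6% ± 17.1 to 16.8% ± 7.41 (adjusted p = 0.0105), and OR52N5, an olfactory receptor, from 82.7% ± 21.6 to 12.8% ± 15.6 (adjusted p = 0.00682). CD69, an early activation marker of lymphocytes, went from 73.8% ± 21.5, with control replicate 4 apart at 41.7%, to 13.4% ± 9.51 (adjusted p = 0.0317). For each of these 4 genes all 4 EPZ libraries lay below all 4 control libraries, which the naming rule requires. Over all tested genes the 2 groups did not overlap in 345 (8.41%). Among the genes that rose, LRRC38, an auxiliary potassium channel subunit (chromosome 1, 13474973 to 13514003), went from 7.95% ± 9.0 to 34.8% ± 2.70 (adjusted p = 0.0253). The zinc finger gene ZNF560 went from 28.3% ± 16.3 to 61.1% ± 12.6 (adjusted p = 0.0435). GRM6, a glutamate receptor of the retina, and MSANTD5 had no island in control and reached 18.8% ± 3.97 and 33.5% ± 20.6 (adjusted p = 0.0375 for each). GRM6 (178978327 to 178995320) and MSANTD5 (178691534 to 178707472) lie near each other on chromosome 5. The zinc finger genes ZFP2, ZNF454 and ZNF879 of that stretch also rose in the main effect of the EZH2 inhibitor, so these may not be separate changes. The fifth gene that rose, OR3A1, fell outside the naming rule and was added after its values were seen.

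By list, EPZ lowered coverage of 2 of 31 tested neuronal genes (5 adjusted over the list alone). These were STMN2, a neuronal microtubule regulator, from 48.2% ± 7.35 to 23.3% ± 9.43 (n = 4, adjusted p = 0.0364), and SCN2A, a voltage-gated sodium channel, from 49.1% ± 8.15 to 20.3% ± 8.43 (adjusted p = 0.0268). Of 14 haematopoietic genes 2 fell (3 adjusted over the list alone): CD3E, of the T cell receptor complex, from 59.4% ± 9.21 to 20.5% ± 14.4, and LMO2, a transcriptional adaptor of blood stem cells, from 66.6% ± 7.62 to 42.0% ± 1.91 (adjusted p = 0.0359 and 0.0271). HOXD1 was the 1 HOX gene of 6 to fall (1 adjusted over the list alone), from 40.2% ± 12.3 to 9.05% ± 6.57 (adjusted p = 0.0253). Of 8 tested genes reported as silenced by EZH2, 1 fell, again STMN2 (2 adjusted over the list alone). Of 9 imprinted genes 1 fell (1 adjusted over the list alone), the growth suppressor PLAGL1, from 29.2% ± 6.65 to 9.13% ± 2.82 (adjusted p = 0.0438). In 4 lists with no call over all genes, 1 member each was lower adjusted over the list alone: signalling ligands, the p38 pathway, hepatocyte and germline genes. No list passed camera, with a lowest adjusted p of 0.183 for keratinocyte genes. The median difference over all tested genes was -4.42 points, and the split of 5 higher and 125 lower became 35 and 69 with covered length as a covariate, 4 and 10 with lists of equal length, and 0 and 2 at the gene ends. The total of 130 became 81 with a replicate block, 57 without the narrowest libraries and 25 in a fit of the 2 groups. Without control replicate 1, 2, 3 and 4 it was 21, 11, 11 and 417. Without EPZ replicate 1, 2, 3 and 4 it was 19, 12, 70 and 204, and without P38i replicate 4 it was 232.

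P38i against control asked what the p38 inhibitor did alone. Coverage rose over 12 genes and fell over 0, with 416 genes at an unadjusted p under 0.05 in limma. SPX, which encodes the peptide hormone spexin (chromosome 12, 21526296 to 21532947), went from 0.631% ± 1.01 covered in control to 41.4% ± 11.2 in P38i (n = 4, adjusted p = 0.000854). TAC3, the neurokinin B precursor, went from 6.50% ± 13.0, with control replicate 1 apart at 26.0%, to 46.4% ± 7.93 (adjusted p = 0.0216). LACRT, a tear glycoprotein, went from 12.7% ± 25.3 to 72.5% ± 12.7 (adjusted p = 0.0227), with control replicate 2 at 50.6% and the other controls at 0. KRT27, a hair keratin, went from 47.4% ± 7.60 to 86.6% ± 15.3 (adjusted p = 0.0216). CCR9, a chemokine receptor of gut-homing T cells, went from 4.52% ± 9.05, with control replicate 1 apart at 18.1%, to 35.7% ± 6.58 (adjusted p = 0.0219). LINGO4 and ZNF853 had no island in control and reached 38.3% ± 13.0 and 24.5% ± 7.0 (adjusted p = 0.0141 and 0.000688). Groups at 0 in every library lower the shared spread of these genes, so their p-values may be too low. Of the genes lower with P38i, none passed; PAX9, a developmental regulator, stood at 0.618% ± 1.24, with P38i replicate 4 at 2.47% and the rest at 0, against 25.2% ± 15.7 in control (adjusted p = 0.266). No member of any of the 15 tested lists passed over all genes, 1 HOX gene of 6 was higher adjusted over the list alone, and no list passed camera (lowest adjusted p = 0.511). The count of 12 became 6 with covered length as a covariate, 7 without the narrowest libraries and 21 with a flank of 5 kb or with no filter. With lists of equal length 1 gene was higher and 3 lower, and none of the 12, of which 4 could be tested, was among them; the count was 0 in a fit of the 2 groups, 31 without control replicate 1, 7, 5 and 28 without P38i replicate 2, 3 and 4, and 8 without control replicate 2.

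Combo against control asked what both inhibitors did together. Coverage rose over 10 genes and fell over 59. CGA went from 81.2% ± 11.2 in control to 31.2% ± 9.04 in combo (n = 4, adjusted p = 0.0192). KRT24, a keratin, went from 78.0% ± 15.6 to 16.2% ± 11.8 (adjusted p = 0.0354), and CCKAR, a cholecystokinin receptor, from 81.1% ± 11.3 to 34.3% ± 16.4 (adjusted p = 0.0422). Among the genes that rose, LRRC38 went from 7.95% ± 9.0 to 43.1% ± 10.7 and GRM6 from 0 to 28.1% ± 6.50 (adjusted p = 0.0131 for each). ZNF595, a zinc finger gene (chromosome 4, 53321 to 88208), went from 0 to 44.6% ± 1.00, with combo replicate 1 apart at 43.1% (adjusted p = 0.0422). MGMT, which repairs alkylated guanine in DNA, went from 5.18% ± 4.88, with control replicate 1 apart at 12.4%, to 20.9% ± 3.52 (adjusted p = 0.0192).

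By list, combo raised 1 of 45 developmental regulators, the head patterning gene OTX2, from 61.9% ± 2.86 to 84.9% ± 5.48 (n = 4, adjusted p = 0.0364; 1 adjusted over the list alone). HOXD1 was the 1 of 6 HOX genes to fall, from 40.2% ± 12.3 to 8.34% ± 10.6 (adjusted p = 0.0351), and 1 fell adjusted over the list alone. STMN2 fell from 48.2% ± 7.35 to 20.9% ± 6.04 (adjusted p = 0.0354), 1 of 31 neuronal genes (3 adjusted over the list alone) and 1 of 8 genes reported as silenced by EZH2 (2 adjusted over the list alone). Adjusted over the list alone, 1 p38 pathway, 1 hepatocyte and 1 imprinted gene were lower and 1 imprinted gene was higher, with no call over all genes. No list passed camera, with a lowest adjusted p of 0.0976 for developmental regulators and keratinocyte genes. The median difference over all tested genes was -1.06 points, and the split of 10 higher and 59 lower became 133 and 224 with covered length as a covariate, 40 and 61 with lists of equal length, and 1 and 2 at the gene ends. The total of 69 became 42 with a replicate block or with no flank, 10 without the narrowest libraries and 4 in a fit of the 2 groups. Without control replicate 1, 2, 3 and 4 it was 36, 6, 8 and 250. Without P38i replicate 2 and 4 it was 43 and 120, and without combo replicate 1, 2 and 4 it was 0, 28 and 4.

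Combo against EPZ asked what the p38 inhibitor added to the EZH2 inhibitor. No gene passed in limma, with 224 at an unadjusted p under 0.05 and a median difference of 3.02 points. KRTAP10-1, a hair keratin-associated protein, stood at 27.3% ± 3.72 covered in combo and 1.19% ± 2.37 in EPZ, where replicate 4 had 4.75% and the rest 0 (n = 4, adjusted p = 0.531). KIAA1755 stood at 15.0% ± 4.24, with combo replicate 2 apart at 8.69%, against 1.63% ± 3.26, with EPZ replicate 3 apart at 6.52% (adjusted p = 0.531). LCE1B, a late cornified envelope gene of skin, stood at 85.3% ± 1.88 against 100% in all 4 EPZ libraries (adjusted p = 0.531). No list member passed, and no list passed camera (lowest adjusted p = 0.550). A fit of the 2 groups called 3 genes and a flank of 1 kb 1 gene, while 1 gene passed without control replicate 4 and 2 without EPZ replicate 4.

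Combo against P38i asked what the EZH2 inhibitor did in cells that also received the p38 inhibitor. Coverage fell over 76 genes and rose over 3. CGA went from 84.2% ± 11.9 in P38i to 31.2% ± 9.04 in combo (n = 4, adjusted p = 0.00904). UGT1A1, which conjugates bilirubin, went from 77.5% ± 21.1 to 13.6% ± 18.6 (adjusted p = 0.0274), and the beta-defensin gene DEFB108B from 48.4% ± 6.19 to 0 in all 4 libraries (adjusted p = 0.00248). HOXD1 went from 36.0% ± 5.97 to 8.34% ± 10.6 (adjusted p = 0.0397) and STMN2 from 45.5% ± 8.66 to 20.9% ± 6.04 (adjusted p = 0.0440). HOXD1 was 1 of 6 HOX genes (2 adjusted over the list alone), and STMN2 1 of 31 neuronal genes (3 adjusted over the list alone) and 1 of 8 genes reported as silenced by EZH2 (2 adjusted over the list alone). With no call over all genes, 2 of 14 haematopoietic genes and 1 p38 pathway, 1 luminal and 1 antigen presentation gene were lower adjusted over the list alone. The 3 genes that rose were LRRC38, from 18.7% ± 4.83 to 43.1% ± 10.7 (adjusted p = 0.0373), the zinc finger gene ZNF454, from 16.8% ± 8.34 to 44.1% ± 10.8 (adjusted p = 0.0412), and GRM6, whose window overlaps that of ZNF454.

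Relative to other genes, developmental regulators and imprinted genes lay higher in combo than in P38i by camera (adjusted p = 0.0275 for each). Neither held with an estimated correlation (adjusted p = 0.941) or with covered length as a covariate (adjusted p = 0.290 and 0.313). No member of either list passed. The developmental list itself had a median difference of -1.22 and a mean of -1.21 points, against a median of -5.14 points over all tested genes. The split of 3 higher and 76 lower became 25 and 43 with covered length as a covariate, 6 and 6 with lists of equal length, 1 and 27 at the gene ends, and 0 and 35 after an arcsine transformation. The total of 79 became 45 with a replicate block, 14 without the narrowest libraries and 43 in a fit of the 2 groups. Without P38i replicate 1, 2, 3 and 4 it was 29, 23, 16 and 231. Without combo replicate 1, 2, 3 and 4 it was 29, 21, 49 and 30.

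The main effect of the EZH2 inhibitor set the 8 EPZ and combo libraries against the 8 control and P38i libraries. Coverage fell over 642 genes and rose over 36. The 2 sides did not overlap in only 65 of all tested genes (1.58%), of which 64 were called. Most called genes thus overlapped between the sides, while the genes in this paragraph were named among those that did not. CGA stood at 28.8% ± 13.5 with the inhibitor and 82.7% ± 10.8 without it (SD, n = 8; adjusted p = 0.000463). ALDH1A1, a retinaldehyde dehydrogenase, went from 59.4% ± 16.3 to 17.4% ± 8.02, and FGF7, a growth factor for epithelial cells, from 47.0% ± 14.1 to 9.90% ± 7.11 (adjusted p = 0.00193 for each). FIGLA, an oocyte transcription factor, went from 60.8% ± 16.2 to 21.4% ± 9.09 and RGS13, a regulator of G protein signalling, from 81.7% ± 11.8 to 32.2% ± 17.7 (adjusted p = 0.00193 for each). PRR23C went from 34.0% ± 14.4 to 0 in all 8 libraries (adjusted p = 0.000732). LRRC38 rose from 13.3% ± 8.80 to 39.0% ± 8.48 (adjusted p = 0.00193).

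Of 31 neuronal genes tested, 10 fell with the EZH2 inhibitor and 0 rose (10 adjusted over the list alone), where 15.6% of all tested genes fell, and the list did not pass camera (adjusted p = 0.743). Among them were SCN2A and SCN1A, near each other on chromosome 2, and STMN2: SCN2A went from 48.6% ± 8.52 to 22.6% ± 7.23, SCN1A from 37.7% ± 10.5 to 14.1% ± 4.12 and STMN2 from 46.9% ± 7.57 to 22.1% ± 7.44 (n = 8; adjusted p = 0.00242, 0.00377 and 0.00262). Of 14 haematopoietic genes 3 fell (3 adjusted over the list alone): CD3E from 61.9% ± 11.2 to 29.2% ± 16.4, LMO2 from 69.2% ± 7.81 to 46.7% ± 6.94, and IKZF3, a lymphoid transcription factor, from 46.9% ± 10.1 to 25.7% ± 6.42. Of 45 developmental regulators 4 fell and 1 rose (2 and 1 adjusted over the list alone). NKX6-1 went from 17.6% ± 11.1 to 3.31% ± 3.99, GATA4 from 37.8% ± 10.4 to 23.5% ± 6.38, SOX17 from 26.9% ± 15.5 to 5.01% ± 14.2 and TBX20 from 63.2% ± 13.4 to 44.3% ± 7.14, while OTX2 rose from 66.8% ± 9.65 to 81.6% ± 5.26 (adjusted p = 0.0282, 0.0435, 0.0486, 0.0273 and 0.0139). At its gene ends TBX20 had a difference of 6.86 points. For SOX17 the SD with the inhibitor is so far above the mean that nearly all its coverage there lies in 1 library. Of 21 signalling ligands 2 fell (1 adjusted over the list alone), the Wnt antagonists DKK2, from 39.97% ± 11.8 to 19.2% ± 5.56, and SFRP2, from 35.3% ± 13.4 to 18.3% ± 6.15. HOXD1, 1 of 6 HOX genes (2 adjusted over the list alone), went from 38.1% ± 9.19 to 8.69% ± 8.19.

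Of 8 genes reported as silenced by EZH2, 2 fell (4 adjusted over the list alone): STMN2 and BMPR1B, a BMP receptor, from 40.7% ± 11.9 to 19.2% ± 3.06 (n = 8, adjusted p = 0.00830). The 1 of 10 luminal genes to fall (1 adjusted over the list alone) was ESRP1, a splicing regulator of epithelial cells, from 76.3% ± 10.7 to 52.8% ± 10.3 (adjusted p = 0.00929). The 1 of 3 p38 pathway genes to fall (1 adjusted over the list alone) was MEF2C, a transcription factor phosphorylated by p38, from 14.8% ± 6.43 to 3.06% ± 2.93 (adjusted p = 0.00968). Of 15 hepatocyte genes 2 fell (1 adjusted over the list alone): ALB, from 55.6% ± 22.1 to 23.6% ± 9.29, and TAT, a tyrosine aminotransferase, from 38.2% ± 14.9 to 16.6% ± 14.8. The meiotic gene SYCP1 was the 1 of 8 germline genes to fall (1 adjusted over the list alone), from 86.6% ± 6.05 to 68.1% ± 12.2. HLA-F among 11 antigen presentation genes and the desmosomal DSG1 among 14 keratinocyte genes also fell, from 14.8% ± 9.34 to 3.82% ± 3.18 and from 35% ± 11.6 to 16.0% ± 12.3, each with 0 adjusted over the list alone. Of 9 imprinted genes PLAGL1 fell from 26.5% ± 8.50 to 10.8% ± 5.01, and ZIM2, a zinc finger gene, rose from 12.6% ± 8.04 to 31.0% ± 10.7 (1 and 2 adjusted over the list alone). In the 7 inflammatory and 3 invasion genes tested no member passed. The Polycomb, cell cycle and housekeeping lists had 1 tested member each and entered no list test.

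By camera, keratinocyte and imprinted genes lay higher than other genes with the EZH2 inhibitor (adjusted p = 0.0403 for each). Neither held with an estimated correlation (adjusted p = 0.970) or with covered length as a covariate (adjusted p = 0.280 and 0.379). The keratinocyte list had a median difference of 2.00 and a mean of -1.16 points, and the imprinted list had 3.54 and 4.34. The median difference over all tested genes was -4.84 points, which became -1.21 with covered length as a covariate and -1.02 with lists of equal length. The split of 36 higher and 642 lower became 127 and 260 with the covariate, 70 and 95 with lists of equal length, 6 and 64 at the gene ends and 15 and 352 without the narrowest libraries, and the total of 678 became 419 without P38i replicate 3.

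The EZH2 inhibitor was tested in separate libraries with and without the p38 inhibitor. Across 4104 genes, which are not independent replicates, the EPZ minus control difference correlated with the combo minus P38i difference (Pearson r = 0.510, Spearman rho = 0.516), and these share no library. In 100 random assignments of the libraries to groups, the real one included, the highest other r was 0.322. Of the genes lowered in each, 22 were shared, in a fit whose spread per gene the contrasts share, and LRRC38 and GRM6 were the 2 higher in both. Of the 130 genes called in EPZ against control, 129 had the same sign in combo against P38i, where 76.7% of all tested genes were negative and 125 of the 130 were lower genes.

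**Figure D2:**
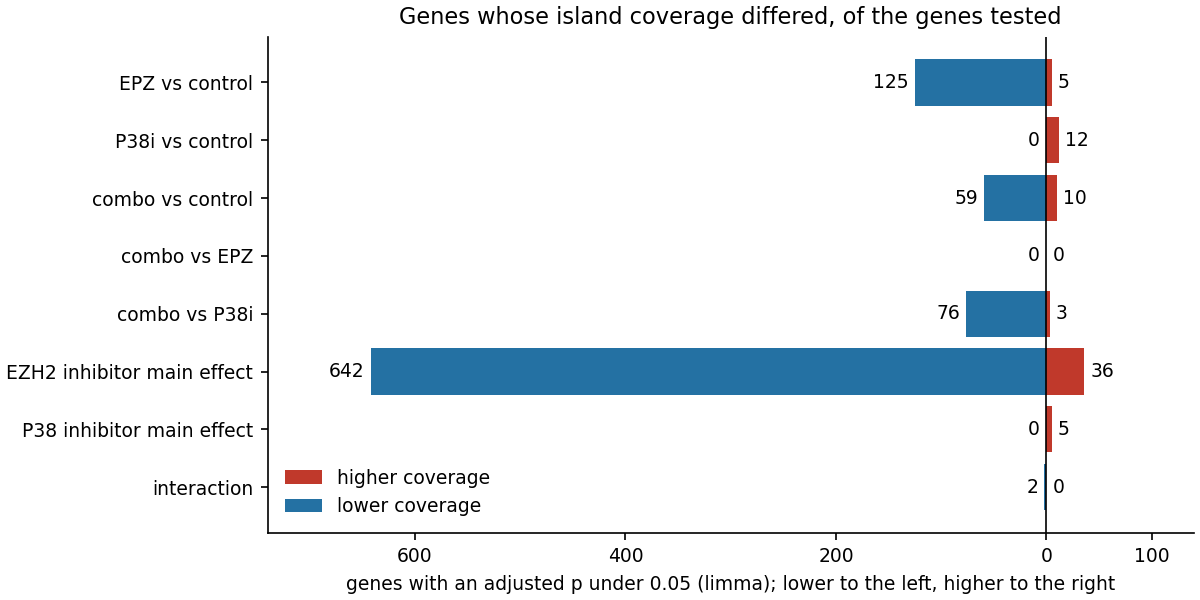
Number of genes with higher and lower H3K27me3 island coverage (limma, adjusted p under 0.05, of 4104 tested) in each comparison. With the EZH2 inhibitor 642 genes were lower and 36 higher over 8 libraries against 8; combo against EPZ had 0.

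**Figure D3:**
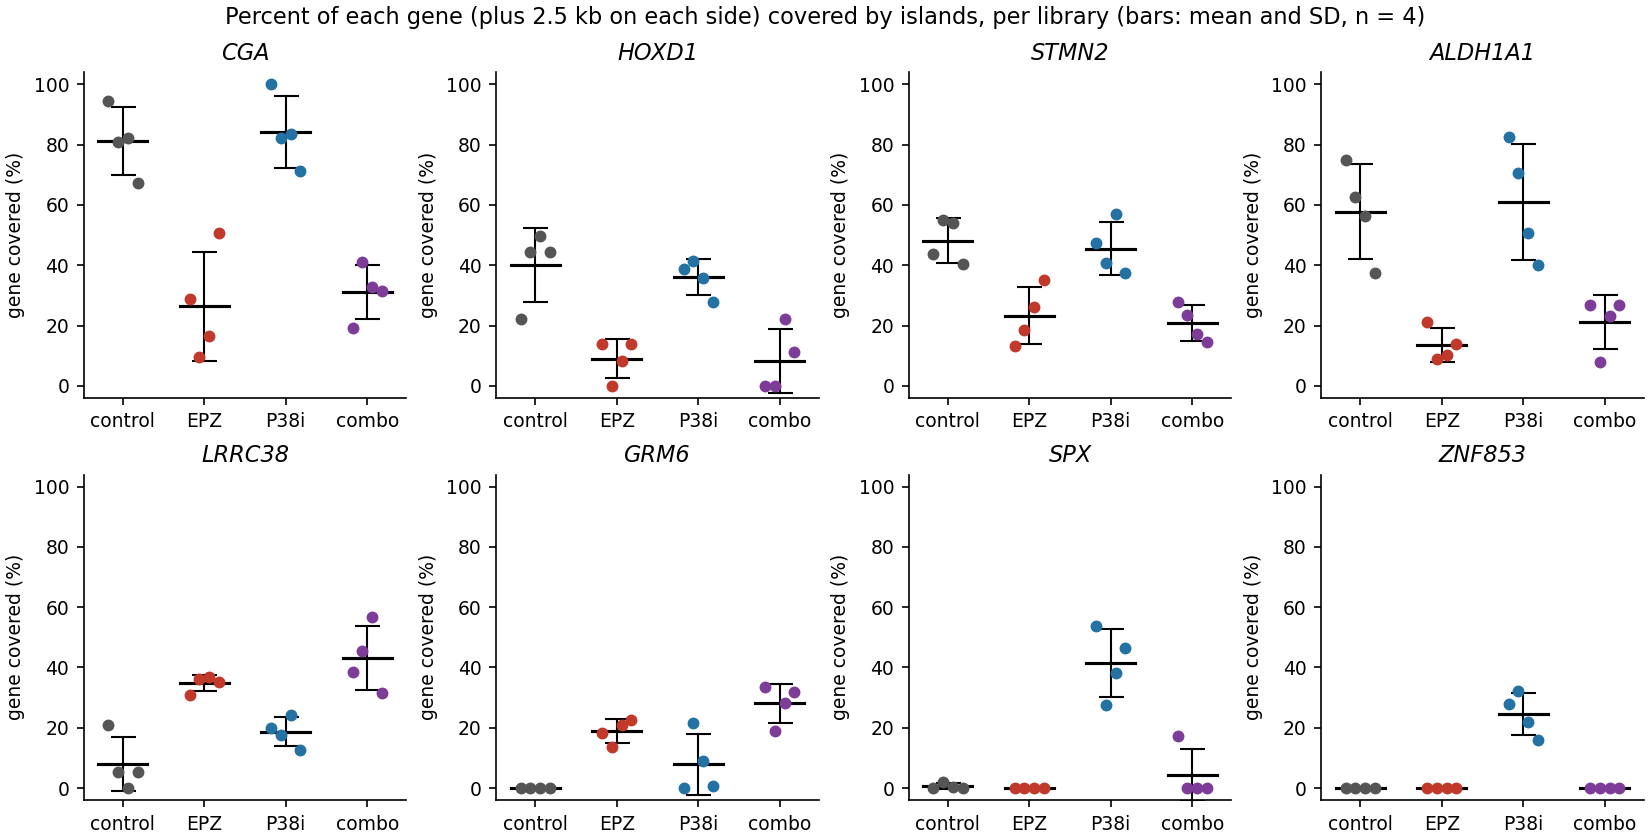
Percent of each gene and 2.5 kb on each side covered by islands in the 16 libraries by treatment, 1 point per library with the mean and SD of each group of 4, for CGA, HOXD1, STMN2, ALDH1A1, LRRC38, GRM6, SPX and ZNF853. CGA lay at 81.2% in control and 26.4% in EPZ, and LRRC38 at 7.95% and 34.8%.

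The main effect of the p38 inhibitor was 5 genes higher and 0 lower, with 544 at an unadjusted p under 0.05 in limma; the 5 did not meet the naming rule and were added after their values were seen. ALOX15, a lipoxygenase, stood at 25.9% ± 4.49 in P38i, 2.47% ± 3.52 in combo, 2.19% ± 4.37 in control and 0 in EPZ (n = 4), a mean of 14.2% with the inhibitor and 1.09% without (adjusted p = 0.0149). SPX stood at a mean of 22.8% with and 0.315% without, from 41.4% ± 11.2 in P38i but 4.29% ± 8.58 in combo, and ZNF853 at 12.2% and 0, from 24.5% ± 7.0 in P38i and 0 in combo (n = 4, adjusted p = 0.0149 for each). LINGO4 stood at 24.4% and 0, from 38.3% ± 13.0 in P38i and 10.4% ± 12 in combo (n = 4, adjusted p = 0.0434). OTOP2, a proton channel, stood at 38.3% and 2.90%, from 48.5% ± 14.5 in P38i and 28.0% ± 19 in combo (n = 4, adjusted p = 0.0439). In the limma interaction, 2 genes passed for a different effect of the p38 inhibitor with and without EPZ. LOC107987433 (chromosome 5, 1285397 to 1289245) stood at 30.5% ± 5.98 in P38i, 17.5% ± 13.1 in EPZ and 0 in control and combo. ZNF853 stood at 24.5% ± 7.0 in P38i and 0 in the other groups (n = 4, limma interaction adjusted p = 0.0212 for each). Both were named after their values were seen. Groups at 0 in every library add no spread, so the shared spread may be too small and these p-values too low. No list passed camera for this main effect or the interaction (lowest adjusted p = 0.589 and 0.816). The P38i minus control and combo minus EPZ differences correlated across genes with r = 0.202 (rho = 0.253), and 8 of the 12 genes raised by P38i had the same sign in combo against EPZ, where 26.4% of all tested genes were negative, so that 8 of 12 does not exceed the overall shift. The count of 5 became 0 with lists of equal length, at the gene ends and in a fit of the groups by this inhibitor alone, 3 with covered length as a covariate or with no flank, 15 with a flank of 5 kb, 2 without the narrowest libraries, 32 without control replicate 1, 3 without EPZ replicate 1, 2 or 3, 2 and 3 without P38i replicate 2 and 3, and 3 and 16 without combo replicate 1 and 2. The count of 2 for the interaction became 0 to 4 with 1 library left out.

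Along the genome, 94064 of 302990 bins of 10 kb were at least 50% covered in any library and 27478 (29.2%) in all 16. In EPZ, 40 bins were gained and 551 lost against control, but 2 of 35 splits gave as many (highest other 815) and limma per bin called 3. Runs of lost bins lay on chromosome 6 from 68630001 to 68660000 within ADGRB3, an adhesion receptor of neurons, on chromosome 11 from 33850001 to 33870000 at LMO2, on chromosome 12 from 15140001 to 15160000 at RERG, an oestrogen-regulated growth inhibitor, and on chromosome 22 from 25790001 to 25810000 at MYO18B. In P38i, 143 bins were gained, as on chromosome 1 from 78880001 to 78900000 at ADGRL4, an endothelial adhesion receptor, and 26 lost, but 13 of 35 splits gave as many (highest other 558) and limma per bin called 0, with 4870 at an unadjusted p under 0.05. In combo, 150 were gained and 346 lost, with as many in 3 of 35 splits and 10 called by limma per bin: a gain ran on chromosome 4 from 40001 to 70000 at ZNF595 and on chromosome 11 from 133340001 to 133360000 at the cell adhesion gene OPCML, and a loss on chromosome 12 from 20360001 to 20380000 at the phosphodiesterase gene PDE3A. Combo gained 183 and lost 27 against EPZ, and gained 88 and lost 434 against P38i, with as many in 7 and 2 of 35 splits and 1 and 3 called by limma per bin. None of these 5 counts can be told from chance, so the regions named are examples of the rule, not tested changes. Over 8 libraries against 8, limma called 957 of 91051 bins lower and 83 higher with the EZH2 inhibitor.

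**Figure D4:**
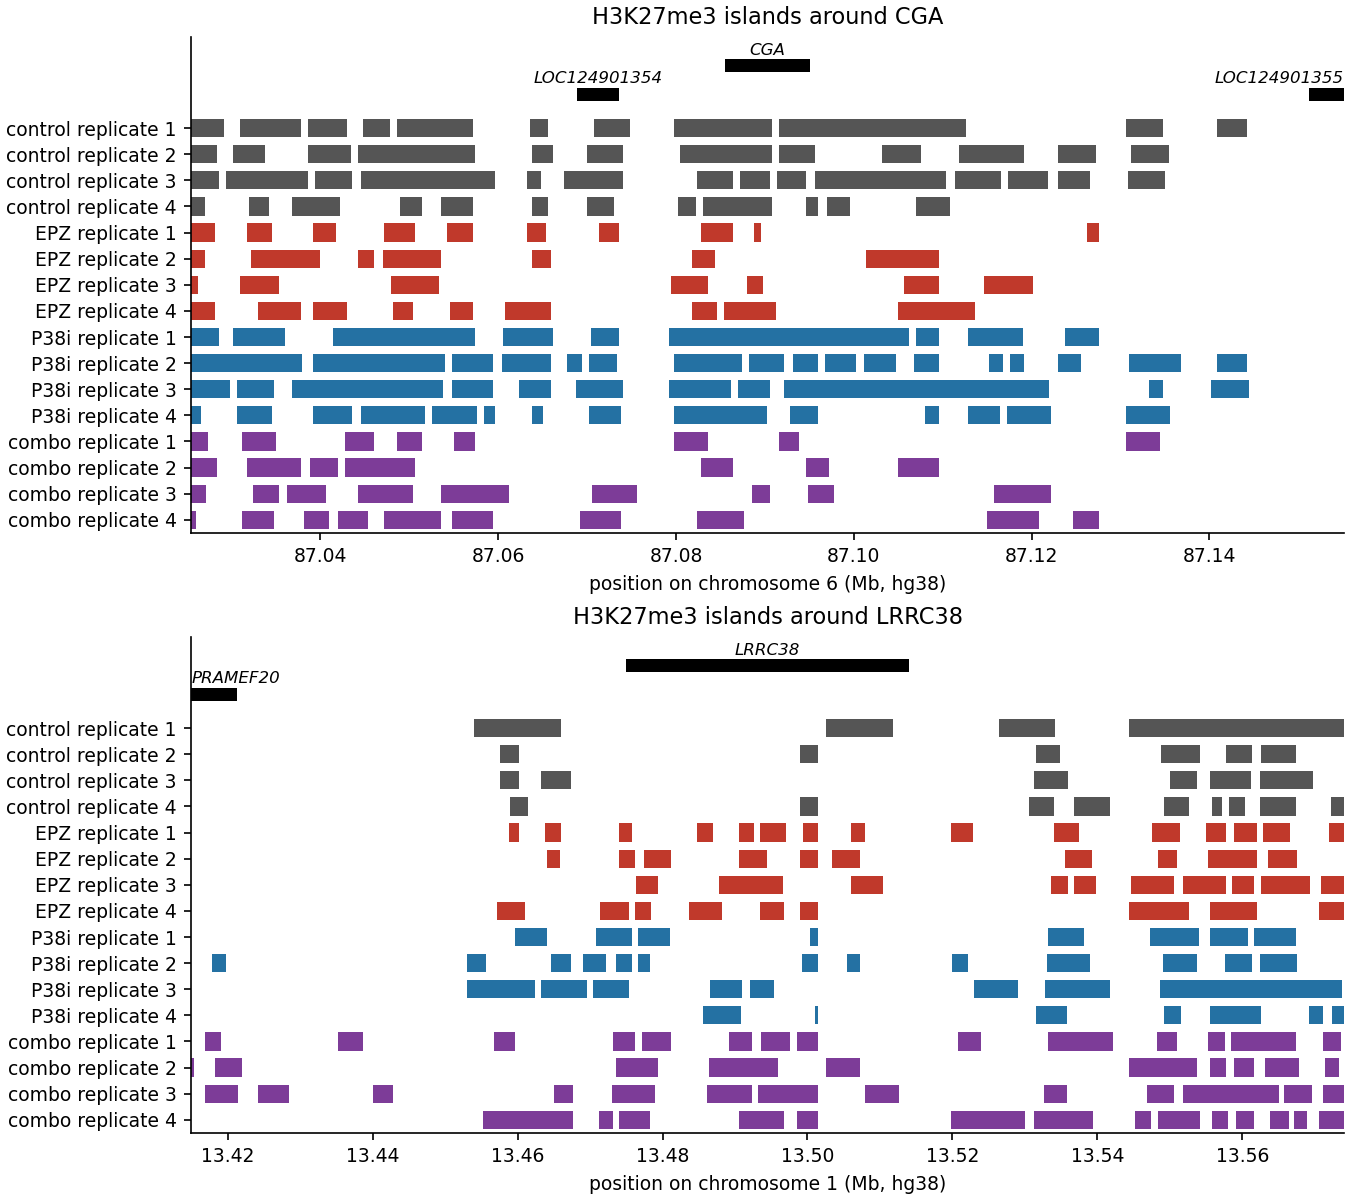
Islands of each of the 16 libraries around CGA on chromosome 6 and LRRC38 on chromosome 1, with the genes of each region, positions in Mb on hg38; each line of bars is 1 library, coloured by treatment. Islands over CGA cover a mean of 82.7% of its window in the 8 libraries without the EZH2 inhibitor and 28.8% in the 8 with it.

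Libraries shared much of the called genome whatever the treatment: the Jaccard index of the 120 pairs ran from 0.568 to 0.724, with a median of 0.619. Within groups minus between groups, it differed by 0.0200 for EPZ and control, 0.00262 for P38i and control and 0.0216 for combo and control. It differed by 0.00217 for combo and EPZ and 0.0170 for combo and P38i. Of 35 splits, the number as large was 2, 11, 1, 7 and 1 in that order. The splits of combo against control and against P38i passed, but neither did with islands matched by 50% reciprocal overlap (exact p = 0.0571 for each). By that measure the differences were 0.0283 and 0.0228, which are not smaller. Without 1 library the Jaccard difference ran as low as 0.0124 for combo against control (control replicate 3). For combo against P38i it ran as low as 0.00539 (P38i replicate 1).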

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

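All tests of explanations in this part were chosen after the result was seen, except the tests at equal covered length in separate libraries, of gene density and of called length for the zinc finger genes, and the splits for the interaction.

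In 10 of 80 groups of 4 libraries tested, 1 library lay far from the other 3, against about 1 in 20 by chance; over all 94 named genes it was 52 of 350, and the smaller set was kept after that count was seen. The values were 41.7% coverage of CD69 in control replicate 4, 26.0% of TAC3 and 18.1% of CCR9 in control replicate 1, and 50.6% of LACRT in control replicate 2. They were 2.47% of PAX9 in P38i replicate 4, 43.1% of ZNF595 in combo replicate 1, 12.4% of MGMT in control replicate 1, 4.75% of KRTAP10-1 in EPZ replicate 4, and 8.69% and 6.52% of KIAA1755 in combo replicate 2 and EPZ replicate 3. For TAC3, CCR9, LACRT, PAX9, KRTAP10-1 and KIAA1755 in EPZ, the other 3 libraries were at 0, where any single island stands apart.

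The change with P38i differed with and without EPZ by -48.0 points for LOC107987433 and -24.5 points for ZNF853, by the interaction in limma. In 7 of 100 random assignments of the libraries to 4 groups as many genes were called, with 277 in the highest other, so chance is not excluded for this count of 2. The assignment with 277 set 7 of the 8 libraries with the EZH2 inhibitor on 1 side of its interaction contrast and 1 on the other, but another assignment with that layout called 0, so what set it apart was not found.

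On chromosome Y, which no comparison used, 11 islands were listed in EPZ, 9 in combo, 1 in P38i and 0 in control. They were in 8 of 8 libraries with the EZH2 inhibitor and 1 of 8 without (Fisher's exact p = 0.00140), 91.4 kb in all with the inhibitor. Why was not tested, so a change with the inhibitor in background or in the mapping of repeats stays open, here and for the lower genes and zinc finger genes weighed below.

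The first pattern weighed was the lower coverage of 642 genes with the EZH2 inhibitor; against less called length as its whole cause, 40.3% of them (259) stayed called with covered length in the fit. At equal length 16.2% stayed called (91 of 561), the other 470 going from a median of -17.5 to -8.97 points, while the differences in separate libraries still correlated across genes (r = 0.375, highest other of 100 random assignments 0.196). Against the narrowest library of each group as its cause, 51.5% of the lower genes tested (330 of 641) stayed called without them. The other 311 genes kept their difference, with a median of -13.4 points before and -14.1 points without these libraries. Their mean standard errors were 4.37 and 5.20. Since a library was left out of every group on both sides, this speaks only to those libraries. It does not test a difference in covered length between the sides. For the 383 genes no longer called with covered length in the fit, the median difference went from -15.3 to -10.5 points with mean standard errors of 4.74 and 4.53; this bound was set after the value was seen, and the median lay more than 2 but under 3 standard errors below 0, so a call lost through a smaller difference cannot be told apart from less called length there. Inhibition of EZH2 remains a candidate explanation for the 259 genes as a set, as a hypothesis, since few calls held at equal length or at the gene ends and read depth is unknown. Covered length is itself what an EZH2 inhibitor would reduce, so holding it equal may remove part of the inhibitor's own effect. For the genes that lost their call these fits therefore cannot tell less called length from EZH2 inhibition.

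The second pattern was the set of zinc finger genes with higher coverage with the EZH2 inhibitor, 18 of 87. Against gene-dense regions as the cause, 0.599% of other genes with a like number of genes within 1 Mb rose (7 of 1169), and against reads shared between paralogs, 0.631% of 5 other families of clustered paralogs rose (2 of 317). Neither set was matched to the zinc finger genes in starting coverage. Olfactory receptor genes, 207 of the 317, had a mean of 75.7% in control replicate 1, where zinc finger genes had 34.6%. These 2 tests therefore do not speak to starting coverage. Against less called length, the median difference of the zinc finger genes was 9.64 points at equal length and 7.23 with covered length in the fit. For all tested genes it was -1.02 and -1.21. In the main fit the medians were 3.10 points for the zinc finger genes and -4.84 for all tested genes. Trimming by island width also raised the medians of the other gene families, as keratin-associated genes from -3.16 to 6.68 points. Part of the 9.64 points may therefore come from the trimming. Mean zinc finger coverage minus that of all tested genes was -8.78 ± 1.29 points in the 8 libraries with the inhibitor and -20.4 ± 1.72 in the 8 without, a difference of 11.6 points (permutation p = 0.000155, the smallest these permutations can give), of which 5.46 points were a higher zinc finger mean (33.6% ± 4.36 against 28.1% ± 4.77, overlapping, exact p = 0.0334) and the rest a lower mean of all tested genes (42.3% ± 4.18 against 48.5% ± 5.63, exact p = 0.0289). Higher coverage of these genes relative to others may follow EZH2 inhibition, as a hypothesis found and tested on the same data; depth and mapping of reads remain untested.

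The counts of changed genes were also set against other splits of the same libraries, fitted alone. For EPZ and control 25 genes were called, 1 of 35 splits gave as many and the highest other gave 1; for combo and P38i 43 were called, 1 of 35 gave as many and the highest other gave 13; for the EZH2 inhibitor over 16 libraries 648 were called, 1 of 100 gave as many and the highest other gave 2. Chance among splits of these libraries is excluded at 0.05 for these 3, each taken alone, without adjustment over the comparisons. Whether replicates were separate cultures is unknown, so a chance difference between cultures could not be tested. Chance is not excluded for combo and control, where 4 were called and 2 of 35 gave as many (highest other 29). Nor is it for combo and EPZ, where 3 were called and 3 of 35 gave as many (highest other 3). For P38i and control and for the p38 inhibitor over 16 libraries 0 were called, which all 35 and all 100 splits reach by construction (highest other 3 and 2), so the genes called in the fit of 16 libraries remain untested in this way. For the bins, as many as the 591 gained or lost in EPZ and control came from 2 of 35 splits, with 815 in the split that sets control replicate 4 with EPZ replicates 1 to 3 against the rest. As many as in P38i and control came from 13 of 35 (highest other 558), in combo and control from 3 (531), in combo and EPZ from 7 (355) and in combo and P38i from 2 (524), so chance is not excluded for any of these 5 counts. By limma per bin, the EZH2 inhibitor over 8 libraries against 8 fitted alone gave 1051 bins lower and 89 higher. Of 100 splits 1 gave as many and the highest other gave 1. Chance among splits of these libraries is excluded there at 0.05, with the same limits.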

How the results depend on the processing

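The flanks around the gene span, windows at the gene ends, lists trimmed to equal covered length by island width, and leaving out the narrowest library of each group (control 4, EPZ 1, P38i 2, combo 1) were chosen after seeing the data. The planned settings that need an island score, the stricter part of each list and equal length by score, were not run, because the files hold no score. The EZH2 inhibitor kept more genes lower than higher in every setting run for its main effect, while its count of genes moved with how islands were summed over a gene and with which libraries were used. At the gene ends, the setting nearest to the planned window, 55 of 530 lower genes (10.4%) stayed called. Of the other 475, 456 kept their sign, with mean standard errors of 4.79 points over the gene span and 10.8 at the gene ends. For the p38 inhibitor no count of genes held in every setting. Over the named genes, 98 of 129 results kept their side of the threshold with covered length as a covariate, 94 of 129 with a replicate block, 45 of 109 with lists of equal length, 30 of 117 at the gene ends, and 1568 of 2039 with 1 library left out. At the gene ends SLCO1C1 went from -22.7 to 4.73 points in P38i against control and TBX20 from -18.8 to 6.86 with the EZH2 inhibitor, and at equal length KRTAP9-4 went from -47.7 to 0.641 in combo against P38i. Whether replicate numbers mark related libraries is not known: same-number correlations ran from -0.151 to 0.178 and those of different numbers from -0.204 to 0.164. Leaving out a library eases the rule of all against none for bins, while it moved counts of genes both ways; otherwise the cause was not tested. Read depth, which is unknown, limits all of these values.

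Values below follow the order EPZ, P38i and combo against control, combo against EPZ and combo against P38i where 5 are given. The number of islands in combo against EPZ turned from -389 to 2560 for islands of at least 2 kb and to 4356 without the narrowest libraries. Without these, covered length in P38i against control turned to -5.68 Mb and median width in combo against EPZ to -0.267 kb. With the replicate block, the p38 inhibitor main effect on covered length, 34.4 Mb, passed (exact sign-flip permutation p = 0.0391). Without it the exact permutation p was 0.30, and whether replicate numbers mark related libraries is not known. With islands matched by 50% reciprocal overlap, similarity was -0.00250 for P38i and control, a change of sign, and 0.0283 for combo and control and 0.0228 for combo and P38i, which no longer passed.

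Bins gained or lost were 1138, 421, 1126, 476 and 974 with bins of 5 kb, and 95, 9, 83, 27 and 106 with bins of 50 kb. They were 7490, 4503, 7337, 4765 and 6588 with at least 3 of 4 libraries against at most 1 of 4, and 2086, 658, 1863, 767 and 1246 without the narrowest libraries. By limma per bin they were 3, 0, 10, 1 and 3, while the main effect of the EZH2 inhibitor had 957 lower and 83 higher. With any overlap, P38i against control had 278. At 90% covered, EPZ against control had 322, combo against EPZ 134 and combo against P38i 328. At equal length combo against P38i had 337.

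Genes changed at the gene ends numbered 2 in EPZ against control, 3 in combo against control, 28 in combo against P38i, 70 and 0 for the EZH2 and p38 inhibitor main effects and 0 for the interaction. With lists of equal length they numbered 14 and 4 in EPZ and P38i against control, 12 in combo against P38i, 165 and 0 for the main effects and 0 for the interaction. With covered length as a covariate they numbered 6 and 357 in P38i and combo against control and 387 and 3 for the main effects. Without the narrowest libraries they numbered 57, 7 and 10 in EPZ, P38i and combo against control, 14 in combo against P38i, 367 and 2 for the main effects and 1 for the interaction. With the replicate block they numbered 81 and 42 in EPZ and combo against control, 45 in combo against P38i and 1 for the interaction. In fits of the groups compared alone they numbered 25, 0, 4, 3 and 43, and 0 for the p38 inhibitor. With a flank of 1 kb they numbered 1 in combo against EPZ and 4 for the interaction; with a flank of 5 kb 21 in P38i against control and 15 for the p38 inhibitor; with no flank 42 in combo against control and 3 for the p38 inhibitor. With no filter they numbered 21 in P38i against control and 5 for the interaction, with the arcsine transformation 35 in combo against P38i, and with plain eBayes 1 for the interaction.

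Lists past camera numbered 2 in combo against P38i and 2 for the EZH2 inhibitor main effect. These became 0 and 0 with an estimated correlation, 0 and 0 with covered length as a covariate, and 1 and 0 with a flank of 5 kb. Of 54 differences in list shares none passed in any setting, and 13 of 108 values under alternatives changed sign. With any overlap these were -2.08, -2.08 and -2.78 points for Polycomb subunits in EPZ, P38i and combo, -0.272 for developmental regulators in combo, 1.25 for luminal genes, 1.97 for antigen presentation genes and 8.33 for imprinted genes in P38i, 2.08 and 1.56 for neuronal genes in EPZ and combo, and 0.893 for germline genes in combo. With a flank of 5 kb they were -1.32 for cell cycle genes and 2.08 for imprinted genes in P38i and 4.00 for keratinocyte genes in EPZ.

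With 1 library left out, the number of islands differed by 603 to 10670, -280 to 8845, 2466 to 10281, -3896 to 5048 and -2472 to 5931. Covered length differed by -97.4 to -35.8, -4.25 to 59.8, -59.4 to 2.20, 20.3 to 57.8 and -84.1 to -37.1 Mb, and in the main effects by -76.0 to -48.4 Mb for the EZH2 inhibitor, the first without control replicate 4, and by 22.4 to 50.2 Mb for the p38 inhibitor. Median width differed by -1.65 to -0.483, -0.95 to 0.183, -1.55 to -0.417, -0.417 to 0.517 and -1.02 to -0.15 kb. Similarity ran from 0.00701 to 0.0369, -0.00367 to 0.0169, 0.0124 to 0.0293, -0.00427 to 0.0110 and 0.00539 to 0.0310. Bins ran from 798 to 1661, 264 to 732, 692 to 1364, 352 to 555 and 721 to 1283. Genes changed ran from 11 without control replicate 2 to 417 without control replicate 4, from 5 without P38i replicate 3 to 31 without control replicate 1, from 0 without combo replicate 1 to 250 without control replicate 4, from 0 to 2 without EPZ replicate 4, and from 16 without P38i replicate 3 to 231 without P38i replicate 4. For the EZH2 inhibitor main effect they ran from 419 without P38i replicate 3 to 923 without control replicate 4, for the p38 inhibitor from 2 without P38i replicate 2 to 32 without control replicate 1, and for the interaction from 0 to 4.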

Other observations

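The gene families below and the Fisher's exact tests of them were chosen after the data were seen. Zinc finger genes, most of them transcriptional repressors, were the family with the most genes of higher coverage with the EZH2 inhibitor: 18 of 87 tested rose, at 11 loci, and 4 fell, where 36 of all 4104 genes rose (Fisher's exact adjusted p = 1.27e-20 over 16 tests, with neighbouring genes not independent). ZNF471 on chromosome 19 stood at 56.2% ± 12.1 covered with the inhibitor and 23.5% ± 15.7 without (SD, n = 8; limma adjusted p = 0.00717). ZNF595 on chromosome 4 stood at 38.3% ± 15.7 and 6.32% ± 15.8 (adjusted p = 0.00969), ZNF582 at 51.3% ± 13.8 and 22.6% ± 12 (adjusted p = 0.00969), and ZNF382 at 22% ± 16.2 and 0 (adjusted p = 0.0173). The split of 18 higher and 4 lower was 20 and 2 with covered length as a covariate, 14 and 0 of 69 at equal length, 7 and 1 of 86 without the narrowest libraries and 3 and 0 of 100 at the gene ends.

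Of 18 tested UDP-glucuronosyltransferase genes, which conjugate bilirubin, steroids and drugs, 13 were lower with the EZH2 inhibitor. These 13 lay at 2 loci, since the UGT1A genes overlap. UGT1A1 stood at 14.6% ± 14.7 with the inhibitor and 70.6% ± 21.9 without (n = 8, limma adjusted p = 0.00225). Of 8 sodium channel genes 5 fell, all at 1 locus on chromosome 2 with SCN1A, SCN2A, SCN3A, SCN7A and SCN9A. SCN9A, a channel of pain-sensing neurons, stood at 9.57% ± 3.69 and 27.4% ± 7.06 (adjusted p = 0.00307). Fisher's exact tests, which take genes as independent, say nothing for these 2 families at 2 loci and 1. At the gene ends 3 of 17 of the glucuronosyltransferase and 0 of 7 of the sodium channel genes passed, and with lists of equal length 1 of 13 and 2 of 8. In the other families 20 of 207 olfactory receptor genes fell and 2 rose, 4 of 16 beta-defensin, 4 of 12 GABA receptor, 2 of 45 keratin-associated and 2 of 31 protocadherin genes fell, and none of these passed its Fisher's exact test.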
